A study of Mus musculus with 2 samples.

How the data were processed

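Gene expression was measured in mouse liver after intravenous adenovirus. C57BL/6J mice aged 2 months received 1000000000 plaque-forming units of an empty vector (Ad-control) or of a vector carrying PDK4 (Ad-PDK4), and livers were taken on day 3, per the labels. Livers of 4 mice (Ad-control) and 3 mice (Ad-PDK4) were combined within each group before labelling, and 10 ug of each pool gave biotin-labelled cRNA by the Affymetrix procedure. Each group is therefore 1 array of 1 pool. The spread between animals cannot be measured, and no p-value was computed for any difference.

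The deposited table holds 1 signal intensity per probe set (a set of short probes for the same transcript) for 45101 probe sets on each array. The summary method, background correction and software are not given in the sources used here. The deposited intensity values are linear, and range from 0.2 to 134096 on the Ad-control array and from 0.1 to 136056 on the Ad-PDK4 array. Their medians are 93.6 and 100.1. On both arrays the mean without the highest and lowest 2% of probe sets is 500, the value that a scaling of each array to a common target gives. With the average of each array fixed in this way, every difference is relative to the other transcripts of the same pool. Detection calls and scanner images were not used here.

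Gene names came from the platform annotation supplied with the table. Of 35890 annotated probe sets, 34958 carried 1 gene symbol and 932 carried several; the latter were not named. Symbols were checked through the Entrez identifier against the mouse RefSeq gene table (assembly GRCm38.p6), where 34754 of the 34958 were found and 0 symbols had to be changed. After 64 control probe sets were set aside, 45037 remained, of which 34945 named 18193 genes and 10092 had no single gene name here. No coordinates are given because the array table names no genome build.

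Signals were put on the log2 scale. A floor was set at the 50th percentile of the non-control probe sets of each array, a signal of 93.4 on the Ad-control array and 99.9 on the Ad-PDK4 array. The log2 difference, Ad-PDK4 minus Ad-control, was centred on its median over the 20151 probe sets at or above the floor on both arrays, a shift of -0.01. Each gene was represented by its probe set with the highest mean log2 signal. A gene under the floor on 1 array has only a bound, the brighter signal against the floor of the other array, and is written "at least N-fold". A gene under the floor on both arrays has no difference.

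With no replicates, the error scale used was the disagreement between probe sets of the same gene. Its pooled SD was 0.35 on the log2 scale over 4326 genes with more than 1 measured probe set. This covers only error that differs between probe sets of the same gene. Error shared by all probe sets of a gene, such as error from labelling a pool or hybridizing an array, is left out. So is the variation between mice. The spread of the differences across genes depended on brightness. The SD of the log2 difference was 0.53 over the 2077 dimmest genes (mean signal 98.7 to 236) and 0.34 over the 2078 brightest (mean signal from 2259). These SDs hold any real differences between the pools as well as error. The number of arrays limits the precision.

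Before the data were examined, 39 gene lists (796 genes) were fixed for liver metabolism, responses to virus and stress, and markers of cell types that liver tissue could hold. Of these genes, 714 were matched to a named probe set; the others are not analysed here. For each list the median log2 difference of the members above the floor on at least 1 array was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these 2 arrays, since genes of a list are not independent and pools were not replicated. Of 39 lists of independent genes, 1.95 would fall outside the middle 95% by chance, and this number does not hold for lists of related genes. Members at least 1.5-fold higher or lower were counted.

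The genes named were also fixed beforehand: Pdk4 and its paralogs, the 12 highest and 12 lowest genes measured on both arrays, the 5 largest bounds in each direction, the 2 highest and 2 lowest members of each list, and 8 regulators of liver metabolism. Of 62 named genes with more than 1 measured probe set, 21 had probe sets on both sides of 0, so their directions are not settled: Akt2, Aldoa, Asns, Cd8a, Cxadr, Dlat, Fabp1, Foxo1, Hyou1, Idh3b, Ighm, Itgb5, Ntmt1, Ppara, Rps10, Rps18, Stat2, Tapbp, Uty, Vegfa and Wee1. Genes without a proper symbol were counted and not named. List members were ranked among those measured on both arrays, since values at the floor have no order.

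The calculations were tested on simulated data built from these arrays. The noise was set to the probe set SD, which leaves out error shared by the probe sets of a gene. All 100 genes (100%) simulated with a log2 change of 2 were found at least 2-fold apart in the right direction, and 69% of 100 genes with a change of 1.2. Of 10744 unchanged genes, 0.419% were 2-fold apart. The changed genes were drawn only from brighter genes measured on both arrays, and the noise was the same at every signal. The dimmest genes of the data had an SD of 0.53, which also holds any real differences between the pools. These rates therefore do not describe genes near the floor. Lists of 20 genes were also drawn at random from all simulated genes with a difference, changed genes included. Among 1000 such lists without a shift, each set against 500 random lists, 5.9% fell outside the middle 95%. With a shift of 0.5, 100% lay above it. Lists of related genes were not simulated.

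Alternatives were fixed beforehand too. They were no centring, quantile normalization, intensity-dependent loess centring, floors at the 30th and 70th percentiles, a pseudocount at the 30th percentile with no floor, the median over the probe sets of a gene, removal of probe sets whose name ends in _x_at or _s_at (designs that can match several transcripts), folds of 1.5 and 3, means in place of list medians, and lists restricted to members measured on both arrays. After a first look at the list medians and the genes at each end, 7 further gene lists and 2 alternatives were added, which are used only in the closing section. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.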

Results

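The study compared livers of mice given an adenovirus that carries PDK4 with livers of mice given the empty vector, 3 days after injection. PDK4 is pyruvate dehydrogenase kinase 4, a mitochondrial enzyme that phosphorylates and inactivates the pyruvate dehydrogenase complex and so limits the use of pyruvate in the tricarboxylic acid cycle. The comparison asks which liver transcripts differ between the pool labelled Ad-PDK4 and the pool labelled Ad-control. Whether PDK4 was overexpressed in these livers is not shown by the arrays. It rests on 2 arrays, 1 pool of 4 livers for the control and 1 pool of 3 livers for PDK4, so that n = 1 per group and every value below describes these pools. Of 18193 named genes, 10389 were above the floor on both arrays, 947 only on the Ad-PDK4 array, 785 only on the Ad-control array and 6072 on neither. The log2 signals of the 2 arrays correlated with r = 0.971 across 20151 probe sets, which are not independent replicates. The 3'/5' signal ratio, a measure of RNA integrity, was 4.88 and 5.46 for beta-actin, 0.785 and 0.806 for Gapdh and 9.26 and 7.96 for pyruvate carboxylase on the Ad-control and Ad-PDK4 arrays. All differences are relative to the median probe set. The poly-A spike-in controls, whose amounts are not given in the sources used here, had a median log2 difference of -0.54. The hybridization controls had one of -0.26. List medians between these values and 0 therefore depend on the reference for their direction.

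Pdk4 itself was not higher in the pool labelled Ad-PDK4. Its only probe set gave a signal of 234 on the Ad-control array and 177 on the Ad-PDK4 array, a log2 difference of -0.39. The signal was low, and 50.2% of the 500 genes of closest mean signal lay as far from 0. Whether this probe set reads the transcript made by the vector is not given in the sources used here, so its level neither checks nor contradicts the labels. It does not show overexpression of PDK4 either. For that reason the samples are called by their labels, and each direction below assumes that the labels are right. Pdk1, another kinase of the same complex, was lower by a log2 difference of -0.60, and its 4 probe sets ranged from -0.89 to -0.54. Pdk2 differed by -0.24, and Pdk3 was below the floor on both arrays.

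The other genes of the pyruvate dehydrogenase complex stayed close to the array median. Of 12 measured members of the list of the complex with its kinases, phosphatases and pyruvate carriers, 1 was at least 1.5-fold lower (Pdk1), none (0) was 1.5-fold higher and 11 lay within 1.5-fold. The phosphatase Pdp2 (0.057) and the acetyltransferase subunit Dlat (0.041) were the highest. The list median was -0.16, at percentile 8.28 of random lists, and moved to -0.089 with the floor at the 70th percentile.

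The largest differences between the pools were in cell cycle and exocrine pancreas transcripts. In all, 280 genes were at least 2-fold higher and 76 at least 2-fold lower in the pool labelled Ad-PDK4, and 10033 genes (96.6%) were within 2-fold. At least 4-fold higher were 60 genes, and 0 genes were 4-fold lower. A further 154 genes under the floor on the control array were at least 2-fold higher by their bound, against 32 lower. Among the 2-fold higher genes with several measured probe sets, all probe sets pointed the same way in 57 of 68. The corresponding number for lower genes was 13 of 23. Both counts depend on the floor, and were 83 higher and 20 lower with it at the 70th percentile, where mostly brighter genes remain, and 688 and 257 at the 30th.

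**Figure D1:**
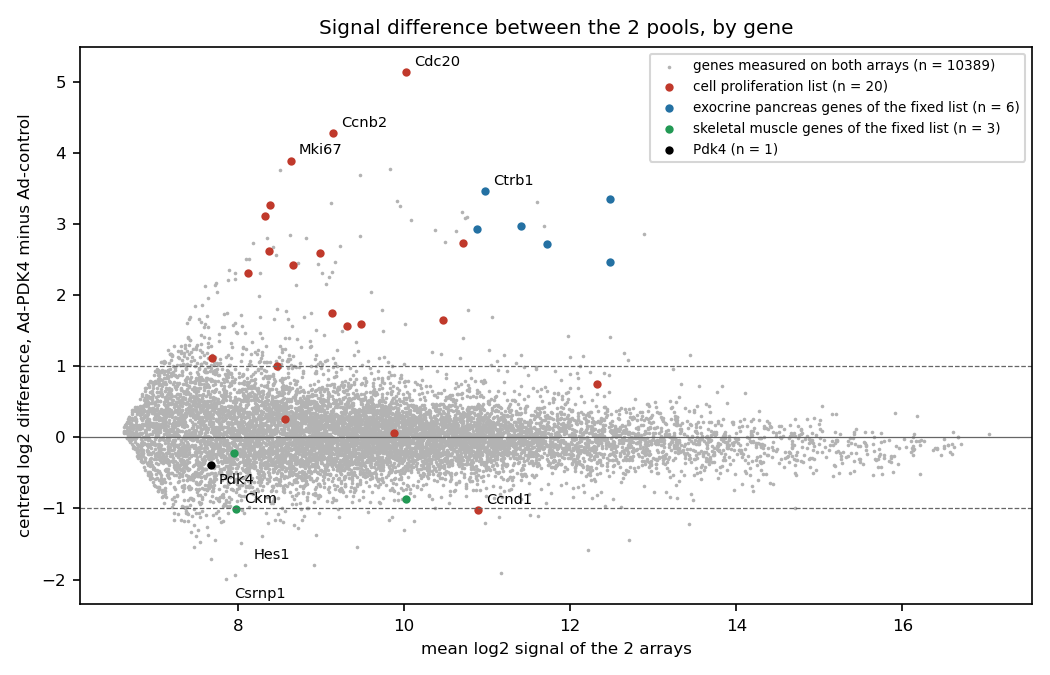
Each point is a gene above the floor on both arrays (10389 genes), with the mean log2 signal on the x axis and the centred log2 difference, Ad-PDK4 minus Ad-control, on the y axis; dashed lines mark 2-fold. Cell proliferation genes (red, 20 of the list) reach 5.13 for Cdc20, 6 exocrine pancreas genes (blue) lie between 2.47 and 3.46, 3 skeletal muscle genes (green) between -1.01 and -0.22, and Pdk4 (black) lies at -0.39.

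Genes of the mitotic machinery led the higher side. Cdc20, an activator of the anaphase-promoting complex, was 35.1-fold higher (signal 176 against 6118), and its other probe set measured on both arrays gave a log2 difference of 4.89. Ccnb2, a mitotic cyclin, was 19.4-fold higher, and Mki67, the gene of the proliferation antigen Ki-67, 14.8-fold. The mitotic regulators Cdca3 and Ckap2 were 13.6-fold and 13.5-fold higher, and Birc5, the survivin gene of the chromosomal passenger complex, 9.67-fold. Genes under the floor on the control array included Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, at least 29.0-fold higher. Aurka (Aurora kinase A) and Kif20a (a mitotic kinesin) were at least 15.1-fold and 12.8-fold higher. The brightest probe set of Hmmr, a hyaluronan receptor, was at least 19.0-fold higher, but its only probe set measured on both arrays gave a log2 difference of 2.31. Cox6b2, the testis form of a cytochrome c oxidase subunit, was also among these, at least 21.9-fold higher. Control signals of these genes lay near the floor, so their folds depend on it. With the floor at the 70th percentile Cdc20 and Mki67 had only bounds, log2 differences of at least 4.45 and 2.45. The same held for Ccnb2 (at least 3.15), Ckap2 (2.25) and Birc5 (1.89). Only genes whose value changed by more than the probe set SD are given, so other genes can be at a bound there as well. The bound of Ube2c was 3.27 with that floor and 5.72 with the floor at the 30th percentile.

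Most members of the cell proliferation list were higher in the pool labelled Ad-PDK4. Of 28 measured members, 24 were at least 1.5-fold higher, 3 were within 1.5-fold and 1 was lower. The list median was a log2 difference of 2.15, at percentile 100 of random lists, 95% of whose medians lay between -0.13 and 0.24. The median counts 8 members at their bound, and it was 1.61 with the floor at the 70th percentile and 2.52 at the 30th. The lowest members were Ccnd1, the cyclin of early G1, with a log2 difference of -1.02 (signal 2718 against 1324), and Tk1, thymidine kinase, with 0.061. In the list of p53 targets, Cdkn1a, an inhibitor of cyclin-dependent kinases, was 5.01-fold higher and Phlda3 1.87-fold higher. Fas (-0.74) and Btg2 (-0.35) were the lowest, 4 of 16 members were 1.5-fold higher and 1 lower, and the median of 0.20 lay at percentile 92.7.

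**Figure D2:**
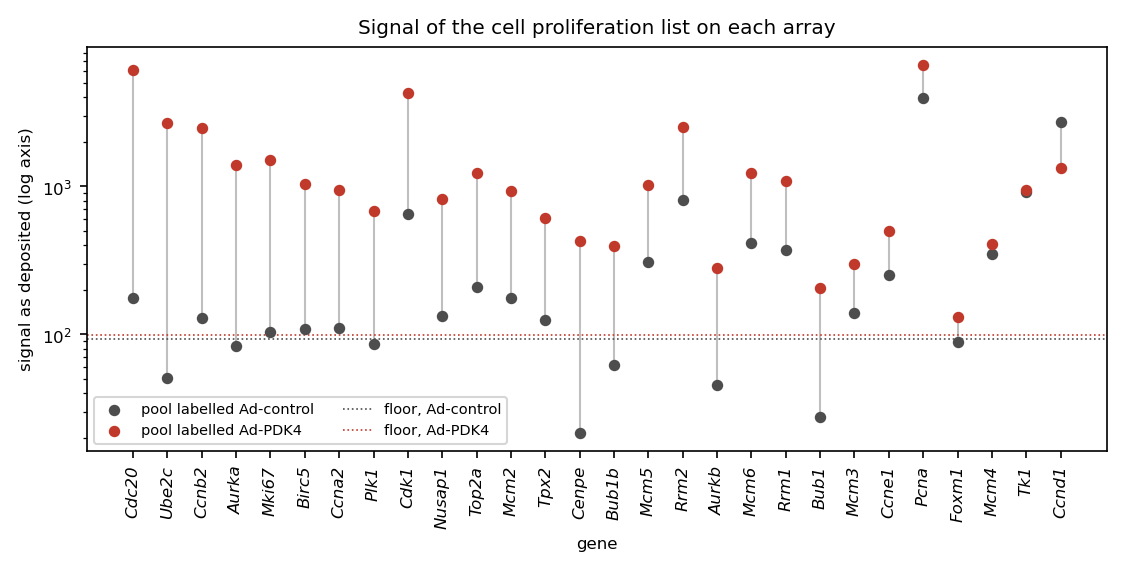
Deposited signal (log axis) of the 28 measured genes of the cell proliferation list on the Ad-control array (grey) and the Ad-PDK4 array (red), ordered by difference; dotted lines mark the floors of 93.4 and 99.9, and each point is 1 pool. Cdc20 has a signal of 176 on the Ad-control array and 6118 on the Ad-PDK4 array, and Ccnd1, at the right, is lower in the pool labelled Ad-PDK4.

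Transcripts of the exocrine pancreas differed together. Ctrb1 (chymotrypsinogen) was higher by a log2 difference of 3.46. Cela3b (an elastase) was 10.2-fold (signal 1792 against 18087), Pnliprp1 (a lipase-related protein) 10.0-fold and Cpb1 (a carboxypeptidase) 9.89-fold higher. Reg2 and Reg1, secreted proteins of acinar cells, were 12.8-fold and 9.51-fold higher. With the floor at the 70th percentile Reg2 had only a bound, a log2 difference of at least 3.18. In the fixed list of pancreas, fat and muscle markers, all 6 measured pancreas genes were higher, with a median log2 difference of 2.96. The 3 skeletal muscle members went the other way, with a median of -0.86. Ckm, muscle creatine kinase, differed by -1.01 (a bound of -0.28 with the floor at the 70th percentile) and Acta1, skeletal alpha-actin, by -0.86. Because its members split in this way, the list median of 2.60 (percentile 100) stands for the pancreas genes alone. The cell cycle genes above were higher in the same pool that held the higher pancreas signal.

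Csrnp1, a nuclear protein gene, had the lowest log2 difference among genes measured on both arrays, -1.99 in the pool labelled Ad-PDK4, followed by Zdhhc12, a palmitoyltransferase, with -1.94 and Tcl1b3 with -1.91, the last on a probe set of the kind that can match several transcripts. Hes1, a transcriptional repressor in Notch signalling, differed by -1.79, Plk3, a polo-like kinase, by -1.79 and Flvcr1, a heme exporter, by -1.71. Phlda1 (-1.59) and Cish (-1.54), a suppressor of cytokine signalling, were bright enough to lie far above the floor. Cox6a2, the muscle form of a cytochrome c oxidase subunit, differed by -1.59, in the pool that also had less of Ckm and Acta1. Clec2d differed by -1.49. With the floor at the 70th percentile Csrnp1, Zdhhc12, Hes1, Flvcr1, Cox6a2 and Clec2d had only bounds, from -0.88 to -0.33. Ntmt1 and Golph3l were at -0.039 and -0.076 with that floor. Only genes whose value changed by more than the probe set SD are given, so others can be at a bound too. The differences of Ntmt1 (-1.55) and Golph3l (-1.47) were not shared by their other probe set (0.036 and -0.27). Cdr2l, Zfp235, Wipf2, Mpp4 and Nfkb2 were under the floor on the Ad-PDK4 array, with bounds between -1.62 and -1.45; the second probe set of Zfp235 gave 0.32. These bounds follow the floor. With it at the 70th percentile Cdr2l was at -0.072, Zfp235 at -0.049 and Wipf2 at 0, and at the 30th Cdr2l was at -3.00, Wipf2 at -2.86 and Nfkb2 at -2.45.

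Lipid synthesis genes had a median slightly below that of the array, with single members on both sides. Of 26 measured genes of fatty acid and triglyceride synthesis, 2 were at least 1.5-fold lower, 2 at least 1.5-fold higher and 22 within that range, and the median of -0.21 lay at percentile 0.55. Fasn, fatty acid synthase, differed by -0.80 (signal 14930 against 8480) and Lpin1, a phosphatidate phosphatase, by -0.58. Pgd, of the pentose phosphate pathway, was higher by 0.72 (0.15 without its _x_at or _s_at probe set), and Dgat1, of triglyceride synthesis, by 0.61. Their regulators Srebf1 (-0.21) and Mlxipl (0.021) differed little. For cholesterol synthesis the median was -0.11 (percentile 13.6; 1 of 21 members 1.5-fold higher, 1 lower). Hmgcs1 (0.64) and Sqle (0.55), both of the synthesis pathway, were the highest, Insig1 (-0.85) and Stard4 (-0.51) the lowest, and Srebf2 gave 0.055. The cholesterol median was closer to 0, at -0.042, with loess centring.

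Amino acid catabolism showed the clearest shift among the metabolic lists. Of 29 measured genes of the urea cycle and amino acid breakdown, 2 were at least 1.5-fold lower, 0 were higher and 27 within 1.5-fold, and the median was -0.27, at percentile 0.05. Hal, histidine ammonia-lyase, differed by -0.87 and Cth, cystathionine gamma-lyase, by -0.65. Asns (0.40) and Bhmt (0.35) were the highest, although Asns gave -0.042 as the median of its probe sets. The loess-centred list median was -0.19.

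Fatty acid oxidation and PPARalpha target genes had a median of 0.047, at percentile 98.2, with 5 of 36 at least 1.5-fold higher and 1 lower. The fatty acid transporter Cd36 (0.99) and the thioesterase Acot2 (0.84) were the highest, and Cyp4a14 (-0.75) and Acot3 (-0.49) the lowest. The mean of this list was 0.14. Ppara itself gave -0.032. Genes of oxidative phosphorylation lay within 1.5-fold in 47 of 47 cases, from Cox5a (-0.36) and Atp5l (-0.35) to Ndufs7 (0.28) and Ndufb3 (0.42). Their median of -0.018 lay at percentile 97.6, in a part of the signal range where differences were below 0 (the 2078 brightest genes had a median of -0.058), and turned to 0.060 with loess centring. The tricarboxylic acid cycle had 17 of 17 members within 1.5-fold and a median of -0.056 and a mean of 0.020 (percentile 56.1), between Sdhc (-0.33) and Idh3b (-0.29) on the low side and Idh2 (0.38) and Cs (0.52), citrate synthase, on the high side.

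In glycolysis 17 of 18 members were within 1.5-fold and 1 was lower, with a median of -0.076 (percentile 23.2), which became -0.22 without probe sets that can match several transcripts. Hk1 (-0.59) and Pfkp (-0.51) were the lowest, and Aldoa (0.17) and Pkm (0.39) the highest. Gluconeogenesis had a median of -0.12 (percentile 21.4), and 12 of 13 members were within 1.5-fold. The other member was Pck2, mitochondrial phosphoenolpyruvate carboxykinase, under the floor on the control array and at least 3.25-fold higher. G6pc, glucose-6-phosphatase, was higher by 0.50, Got1 differed by -0.53, and the coactivator Ppargc1a by -0.58 (3 probe sets, -0.97 to -0.27). Foxo1 gave 0.26, with other probe sets down to -0.15. Ketone body synthesis was measured by 4 genes only, all within 1.5-fold, with a median of 0.16 (percentile 85.6), and 0.34 when probe sets were combined. Fgf21, a fasting hormone, gave 0.58 and Oxct1 -0.0041. Insulin and FoxO signalling had a median of -0.21 (percentile 0.95), with 2 of 21 members higher and 2 lower, but a mean of -0.035. Igfbp1 (0.61) and Akt2 (0.35, or -0.20 without its _x_at or _s_at probe set) were its highest members, and Txnip (-0.80) and Igfbp2 (-0.61) its lowest.

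Bile acid synthesis and transport had a median of -0.047 (percentile 52.8), with 3 of 24 members higher and 2 lower. Cyp8b1 (0.78) and Cyp7b1 (0.73), both hydroxylases of bile acid synthesis, were higher, and the transporters Slco1a4 (-0.80) and Abcb11 (-0.74), the bile salt export pump, were lower. Nr1h4, the bile acid receptor gene, gave -0.041. Lipoprotein genes had a median of -0.091 (percentile 40.4) and 21 of 21 members within 1.5-fold, between Lcat (-0.57) and Apoa5 (-0.50) and, at the top, Apom (0.12) and Mttp (0.13). Drug metabolism genes of CAR and PXR had a median of -0.083 (percentile 32.7; 2 of 20 higher, 2 lower). Cyp2b9 (0.94) and Cyp2c55 (0.70) were higher, and Alas1 (-0.99), the first enzyme of heme synthesis, and Ces2a (-0.64) lower. NRF2 targets had a median of -0.14 (percentile 10.1; 1 of 18 higher, 2 lower), from Osgin1 (-0.86) and Gsta2 (-0.84) to Txnrd1 (0.54) and Cbr3, a carbonyl reductase that was 2.002-fold higher.

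The circadian clock list had a median of -0.35, at percentile 0.03, with 4 of 17 members at least 1.5-fold lower and 0 higher. Per2 (-0.85) and Usp2 (-0.64) were the lowest members measured on both arrays, and Wee1 (0.58, with -0.017 on its other measured probe set) and Hlf (0.34) the highest. Wee1 is also a kinase of the cell cycle. The hour of sampling is not given in the sources used here.

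Acute phase genes were partly higher. Of 28 measured, 8 were at least 1.5-fold higher and 0 lower, with a median of 0.10 (percentile 99.5) and a mean of 0.31. Over the 26 members measured on both arrays the median was -0.010. Lcn2, a siderophore-binding protein, was 3.16-fold higher and Orm2, an orosomucoid, 2.68-fold higher, while Hamp (-0.48) and Crp (-0.40) were the lowest. Interferon-stimulated genes had a median of 0.041 (percentile 51.0), which was -0.026 after quantile normalization, with 3 of 35 higher and 1 lower. Usp18 (0.80) and Oas1a (0.73) were the highest, and Ddx58 (-0.60) and Stat2 (-0.48) the lowest; the median over the probe sets of Stat2 was 0.13. Cytokines and chemokines had a median of -0.21 (percentile 3.91), which was -0.032 as a mean and -0.034 with the floor at the 70th percentile; Ccl4 (0.92) and Ccl5 (0.46) were the highest, Tlr2 (-0.52) and Il1b (-0.43) the lowest, and 1 of 11 was 1.5-fold higher.

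Markers of immune cells gave no common direction. T and NK cell markers had a median of 0.080 (6 measured, 1 lower, percentile 42.9), and -0.053 with the floor at the 30th percentile, between Prf1 (-0.19), Cd8a (-0.061), Thy1 (0.42) and Klrd1 (0.52). B and plasma cell markers gave 0.11 and a mean of -0.024 (5 of 5 within 1.5-fold, percentile 48.6), with Ighm at 0.18, Jchain at 0.11 and Cd79b at -0.47. Neutrophil markers gave 0.20 (6 measured, 3 higher and 1 lower, percentile 62.4), or 0.64 over members measured on both arrays and -0.22 without _x_at and _s_at probe sets, with Ngp (0.81), S100a8 (0.66) and S100a9 (0.61) higher and Elane at -0.22. Macrophage markers gave -0.13 (17 measured, 2 lower and 0 higher by 1.5-fold, percentile 6.77). Among these Vsig4 (-1.19) and the dim Clec4f (-1.13, signal 278 against 126) were the lowest, and Cd68 (0.37) and Adgre1 (0.21) the highest. The other 15 were within 1.5-fold or under the floor on 1 array, so the list does not show a common loss of Kupffer cell markers. Antigen presentation genes gave -0.038 (percentile 46.6; 11 of 11 within 1.5-fold), and 0.045 when probe sets were combined. Tap2 (0.53) and H2-Ab1 (0.38) were the highest, and Tapbp (-0.24) and Cd74 (-0.22) the lowest; without the probe sets that can match several transcripts, H2-Ab1 was under the floor on the Ad-PDK4 array, with a bound of -1.36.

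Hepatocyte markers were within 1.5-fold in 15 of 15 cases, with a median of -0.096 (percentile 52.9) that turned to 0.018 with loess centring. Alb, albumin, gave 0.079, Fabp1 0.045, Rbp4 -0.26 and Cps1 -0.34, and Hnf4a -0.18. Stellate cell and fibrosis genes gave -0.083 (18 measured, 1 higher and 1 lower, percentile 14.1). Des (0.72, but a bound of 0.060 with the floor at the 70th percentile) and Tagln (0.39) were highest and Pdgfra (-0.88) and Ecm1 (-0.50) lowest. Sinusoidal endothelial markers gave -0.18 (16 measured, 1 higher and 1 lower, percentile 3.44), from Cdh5 (-0.68) and Eng (-0.58) to Lyve1 (0.36) and Pecam1 (0.71). Cholangiocyte markers gave -0.28 (5 measured, 1 higher, percentile 5.70), which turned to 0.18 with the floor at the 70th percentile, with Krt23 at 0.86 and Epcam at -0.52. Erythroid markers were represented by 3 genes with a median of -0.43 (percentile 2.48) and a mean of 0.15, and it turned to 0.54 over genes measured on both arrays; Car2, carbonic anhydrase, was 2.83-fold higher and Alas2 gave -0.43.

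**Figure D3:**
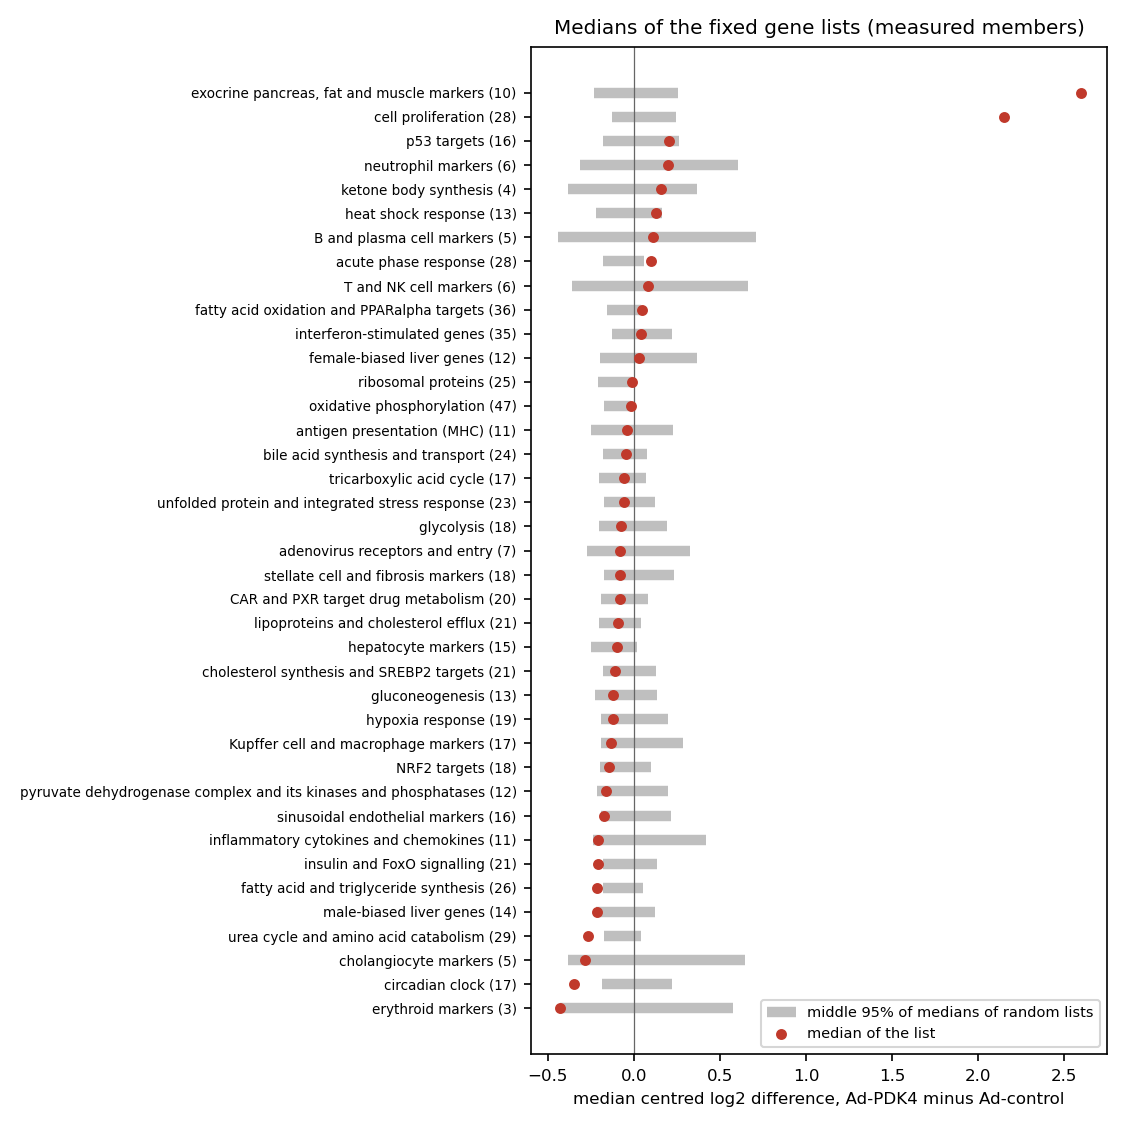
Median centred log2 difference, Ad-PDK4 minus Ad-control, of each of the 39 fixed gene lists (red points, number of measured members in brackets) against the middle 95% of medians of 10000 random lists of the same size matched on mean expression (grey bars). Cell proliferation (2.15) and the list of pancreas, fat and muscle markers (2.60) lie far to the right of their bars.

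The remaining lists lay within the middle 95% of random lists. The unfolded protein and integrated stress response gave -0.056 (23 measured, 1 higher and 2 lower, percentile 34.4), with Sesn2 (0.70) and Pdia6 (0.43) highest and Hyou1 (-0.68) and Dnajc3 (-0.53) lowest; Hyou1 turned to 0.23 on its other design of probe set. Heat shock genes gave 0.13 (13 measured, 1 higher and 1 lower, percentile 95.5), from Cryab (-0.86) and Bag3 (-0.52) to Hspa4l (0.54) and Hsp90aa1 (0.97). Hypoxia genes gave -0.12 (19 measured, 2 higher and 2 lower, percentile 9.22), with P4ha2 (0.83) and Ankrd37 (0.65) at the top and Vegfa (-0.75, with 0.13 on its other measured probe set) and Pdk1 at the bottom. Ribosomal protein genes gave -0.010 (25 of 25 within 1.5-fold, percentile 96.7), and 0.069 with loess centring, from Rps6 (-0.46) to Rpl10a (0.24) and Rps10 (0.32). Genes of adenovirus receptors and entry gave -0.081 (7 of 7 within 1.5-fold, percentile 23.6), with Itgav at -0.38, Itgb5 at 0.22 and Cxadr, the receptor gene, at -0.081. Male-biased liver genes gave -0.22 (14 measured, 2 higher and 2 lower, percentile 2.54), from Serpina4-ps1 (-1.44) and Uty (-0.60, with a probe set at 0.24) to Cyp7b1 and Cyp2u1 (1.07). Female-biased genes gave 0.030 (12 measured, 4 higher and 2 lower, percentile 39.2), with Cyp17a1 2.97-fold and Atp6v0d2 2.05-fold higher and Slco1a4 and Acot3 lowest. Members under the floor on 1 array were not ranked, and some had larger bounds than the members named; those given here and Pck2 were chosen after their values were seen. Gadd45b (insulin and FoxO signalling, log2 difference at least 2.00), Orm3 (acute phase, at least 3.64-fold), Cidec (fatty acid oxidation, at least 2.56-fold) and Slc51a (bile acids, at least 1.97-fold) were higher, and Csf3r (neutrophils, at least 1.996-fold lower), Arntl (circadian clock, -0.93) and Pnpla3 (lipid synthesis, -0.75) lower. Of the 39 lists, 10 lay outside the middle 95%, against 1.95 expected if the genes of a list were independent. They are not, so the 2 numbers cannot be compared as a test. The lists outside include oxidative phosphorylation, acute phase and erythroid markers, whose medians changed sign under some alternatives. The median of 8 lists, none further than 0.096 from 0, changed sign under quantile normalization or loess centring, so these lists have no settled direction: oxidative phosphorylation, interferon-stimulated genes, antigen presentation, T and NK cells, hepatocytes, the unfolded protein response, female-biased genes and ribosomal proteins. The direction of every list with a median below 0 also depends on the reference, since all lay between 0 and the poly-A spike-in median of -0.54.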

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

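All tests below were written down before their own results were seen, except the 2 on Pdk4. The medians over acinar and pan-leukocyte genes measured on both arrays also came after. The patterns themselves had been seen.

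Signals outside the named genes also differed. A control probe set of the array for the mouse B1 repeat family, not used in any comparison, was higher in the pool labelled Ad-PDK4, with a signal of 6693 against 14921 and a log2 difference of 1.17. The 2 controls for the B2 repeat family gave -0.094 and -0.39. Of the 3 controls along the 18S ribosomal RNA, the middle one gave -1.30, with a signal of 292 against 118, and the others 0.18 and 0.28. Among 2661 probe sets measured on both arrays that had no single gene name here, 46 were at least 2-fold higher and 44 at least 2-fold lower.

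The cell cycle genes were higher in the pool labelled Ad-PDK4. An intensity-dependent trend between the arrays is argued against by the loess-centred median of the list, which stayed at 2.13. Faulty or cross-hybridizing probe sets are argued against only for the higher genes that had a further measured probe set. For these, 8 of 8 further probe sets (100%) were at least 1.5-fold higher. Genes with 1 probe set, such as Ccnb2, Mki67, Birc5 and Ube2c, were not covered, nor was Aurka, with 0 probe sets measured on both arrays. An influx of dividing leukocytes stays open. The 16 pan-leukocyte genes had a median of 0.13, with a bootstrap interval over genes from -0.033 to 0.36. That interval includes the limit of 0.26 set for this explanation. Over the 15 of them measured on both arrays the median was 0.029. The brightest, Lcp1 and Srgn, had signals of 3039 against 2986 and 1268 against 1140. An effect of PDK4, a response of 1 or more animals of the pool to the virus, and transcripts brought in with the pancreas signal stay open and were not tested, because each group is a single pool.

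The acinar pancreas genes of the fixed list were higher in the same pool. Pancreatic tissue taken along with a liver is a candidate explanation, tested on acinar genes outside the fixed lists, of which 12 were measured, with a median of 1.19 (bootstrap interval over genes 0.38 to 2.28), 8 of them at least 1.5-fold higher and 1 lower, against a limit of 1 set for it. The median reached that limit, but its interval extends below it. Of the 12 genes, 8 entered at a bound, and a bound can only point towards the array where the gene was measured. Of 16 such genes on the array, those under the floor on both arrays were left out. The median of 1.19 alone therefore does not decide. Only 4 of these genes were measured on both arrays, with a median of 0.71. Of these, Pla2g1b (2.31, signal 139 against 681) and Pnliprp2 (1.24) were higher, while Ctrc (0.19) and Klk1 (-0.065) were within 1.5-fold. This subset leaves out genes under the floor on the control array, such as Gp2 (signal 33.8 against 493) and Cuzd1 (47.1 against 437). Their bounds are minimum values, so the lower median of the subset does not decide. Aqp12 (155 against 28.8), also left out, went the other way. Of 3 measured islet genes none was measured on both arrays: Ins2 (signal 16.3 against 156) was at least 1.68-fold higher, while Pyy (101 against 22) and Pcsk1n (95.9 against 57.6), above the floor on the control array only, did not go with it, so they do not decide. A trend with intensity is argued against by the loess-centred median of 2.97 for the fixed pancreas genes, and a change inside liver cells stays open as untested.

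Pdk4 signal was not higher in the pool labelled for it. Swapped labels with a probe set that reads the vector transcript would need a difference of -1 or lower by the limit chosen here, and the value was -0.39. That lies above the limit by 1.73 times the probe set SD of 0.35, and by about 1 SD of 0.60 among the 500 genes of closest signal, so this argument is weak. A probe set that does not read the vector transcript cannot be excluded or shown, because only 1 Pdk4 probe set could be compared and the insert is not described in the sources used here. For the same reason the arrays do not show whether the pool labelled Ad-PDK4 held vector transcript at all.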

How the results depend on the processing

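The 2 alternatives without listed tissue or cell cycle genes were chosen only after the result was seen. No paired analysis was possible because each group is 1 pooled sample, and for the same reason no replicate could be left out. A value was called moved when it changed by more than the probe set SD (single genes), the bootstrap SE over members (lists) or 1.5-fold (counts). The log2 difference of Pdk4 stayed between -0.46 and -0.32 in every alternative that gave a value; with the floor at the 70th percentile it was below the floor. Of 389 alternative list medians, 358 stayed within their spread, as did 1388 of 1444 alternative values of single genes, where 51 moved. Genes that had no value under an alternative are not in these counts. With the floor at the 70th percentile 29 single genes moved and 126 stayed, and other named genes had no value. The counts of genes at least 2-fold higher and lower stayed within 1.5-fold of 280 and 76 under 5 planned scalings and probe choices, with 243 to 273 and 64 to 97. Without the pancreas and muscle genes of the gene lists they were 271 and 75, and without the listed cell cycle genes too 245 and 74. Genes outside the lists, such as Cpb1, Reg2 and Ckap2, were still counted, so these 2 alternatives do not give the whole share of either group. The counts moved to 688 and 257 with the floor at the 30th percentile, 83 and 20 at the 70th, 1272 and 535 with no floor and a pseudocount, 957 and 540 at 1.5-fold, and 89 and 8 at 3-fold. The cause for the floor is that dim genes enter or leave. Lists moved as follows, and the cause was not tested. With the floor at the 30th percentile cell proliferation was 2.52. At the 70th it was 1.61, pyruvate dehydrogenase -0.089, cytokines -0.034, cholangiocyte markers 0.18 and erythroid markers 0.55. With the pseudocount cholangiocyte markers were 0.17. Loess centring gave oxidative phosphorylation 0.060, fatty acid oxidation 0.10, cholesterol synthesis -0.042, urea cycle and amino acids -0.19, ribosomal proteins 0.069 and, reversed from -0.096, hepatocyte markers 0.018. Quantile normalization gave oxidative phosphorylation 0.033, cholesterol synthesis -0.030, interferon-stimulated genes -0.026, ribosomal proteins 0.071 and hepatocyte markers -0.0051. Means in place of medians gave fatty acid oxidation 0.14, acute phase 0.31, cytokines -0.032 and insulin and FoxO signalling -0.035. The median over probe sets gave ketone body synthesis 0.34, cholesterol synthesis -0.016 and antigen presentation 0.045. Without _x_at and _s_at probe sets glycolysis was -0.22, cholesterol synthesis -0.037, antigen presentation -0.12 and erythroid markers 0.53. Members measured on both arrays gave neutrophil markers 0.64 and erythroid markers 0.54. Single genes reversed in 5 cases: over their probe sets Zfp235 gave 0.32, Asns -0.042 and Stat2 0.13, and without _x_at and _s_at probe sets H2-Ab1 gave a bound of -1.36 and Hyou1 0.23. Signal over background limits the dim genes most, where the floor decides which are counted.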

Other observations

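Gene groups in this part were chosen after the arrays had been looked at, and the test on the cell cycle phases was written before its result was seen. Several skeletal muscle transcripts outside the fixed lists were lower in the pool labelled Ad-PDK4. Of 11 measured, 6 were at least 1.5-fold lower and 1 was higher, with a median log2 difference of -0.65 (bootstrap interval over genes -0.83 to 0.10). Casq1 (-1.14, a bound), Mylpf (-0.90), Myl1 (-0.83), Tnni2 (-0.78) and Mb (-0.76), which encode proteins of muscle fibres, were the lowest, and Tpm2 (1.13) was the highest. Immediate early genes had a median of 0.078, with Ier2 (-0.93), Egr1 (-0.91) and Gadd45g (-0.63) lowest and Junb (0.55) highest, so that the low values of Csrnp1 and Plk3 were not shared by 12 of 15 genes of that kind, which stayed within 1.5-fold.

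Among genes outside the fixed lists, those of G2 and M phase differed more than those of S phase. The 22 G2 and M phase genes had a median log2 difference of 1.66 (21 at least 1.5-fold higher) and 20 S phase genes 0.60 (10 at least 1.5-fold higher). The medians differ by 1.06, with a bootstrap interval over genes from 0.61 to 1.56, and 14 of the G2 and M phase genes enter at their bound. Both medians were higher within the fixed cell proliferation list, split after its values had been seen, at 2.67 over 16 G2 and M phase members and 1.34 over 10 S phase members. A hypothesis is that more cells were in G2 and M phase than in S phase when the livers were taken. Folds also depend on how much of each transcript is present outside these phases, which was not measured, and with 1 pool per group a single animal may account for the difference, so the hypothesis stays open.

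Spike-in transcripts offered another reference. Poly-A spike-ins were lower on the Ad-PDK4 array in 22 of 24 measured probe sets, with a median log2 difference of -0.54, and hybridization spike-ins in 18 of 18, with a median of -0.26. The medians of 27 lists, all those with a median below 0, lay between 0 and the poly-A median. Those of 23 lists lay between 0 and the hybridization median. Against the respective spike-ins, had equal amounts been added, these lists would turn from lower to higher. The amounts added per sample are not given in the sources used here, so the spike-ins were not used for scaling.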
